A study of Bos taurus with 12 samples.

How the data were processed

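RNA was measured in pools of bovine embryos made in vitro from oocytes of adult cows or of prepubertal heifers. Per the labels, total RNA of each pool was amplified with a whole-transcript kit (WT-Ovation Pico), and the biotin-labelled cDNA was hybridized to an Affymetrix bovine genome array. The deposited values are a signal intensity per probe set, which the authors made with MAS5, a method that reads each probe set of an array on its own. The MAS5 version and its settings are not given in the sources used here. The values themselves are on a linear scale. The mean signal of each of the 12 arrays, after trimming 2% of the probe sets at each end, lay between 500.19 and 500.31, which is the MAS5 scaling to a target of 500, and no other adjustment between arrays was found. Each array held 24128 probe sets, of which 112 were Affymetrix controls and 24016 were tested. No column belonged to another series (0 columns), and no pair of arrays shared more than 0.00414% of its values.

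Gene names came from the platform's annotation and were brought up to date through the gene identifier: 13292 probe sets named exactly 1 gene, 86 named several and 10638 named none. The current symbol was looked up by gene identifier for 13263 of them and by accession for 2, 27 were not found and kept their name, and 1 symbol changed. NANOG, CDX2, GATA3 and ZAR1, which were among the planned stage markers, are not named in the annotation used here.

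Signals were analysed as log2(signal + 16). A linear model with a mean for each of the 4 groups was fitted to all 12 arrays with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with trend = TRUE), which left 8 residual degrees of freedom and a prior of 195.66. The comparisons were prepubertal against adult at each stage, the difference between those effects, and blastocyst against 8-16-cell embryos within each donor group. limma's moderated test was two-sided, its p was adjusted by Benjamini and Hochberg over the 24016 probe sets, and a probe set was called at an adjusted p of 0.05. With 3 arrays per group, the number of arrays limits the precision. The standard error of a difference had a median of 1.30 on the log2 scale. Single values per array were compared by exact two-sided permutation tests, which cannot go under p = 0.1 for 3 arrays against 3.

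Signals carry no detection call here. A background was therefore set for each array as the highest of its 27 control probe sets for Bacillus subtilis genes, which have no counterpart in the embryo. The background ranged from 122 to 1664 and the median of the 27 probe sets from 10.45 to 100.82, so the brightest ones set it. Whether these sequences were added to the samples was not checked, and if they were, the background is too high. Where all 3 arrays of the dimmer group were at background, the fold is given as at least the ratio of the brighter group to the dimmer one with each of its signals raised to that array's background. The adjusted p beside it is that of the fit. All other changes are log2 differences with their standard error (SE).

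Genes named in the text followed a rule. For each comparison of groups, the genes taken were those past the threshold whose probe set named 1 gene with a proper symbol, whose 3 arrays of one group all lay above the 3 of the other, and whose brighter group reached the median of all probe sets. The 10 largest per direction were named. Where fewer passed, the smallest unadjusted p with a difference of at least 1 on the log2 scale filled the 10 places, as values that did not pass. The 5 smallest p were named for the difference of the donor effect between stages, and the 4 smallest for each list, along with the stage markers POU5F1, KRT18, IFNT2, GDF9, BMP15 and NLRP5. Others are marked as chosen after their values were seen.

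The 22 gene lists were: maternal and oocyte transcripts, embryonic genome activation, pluripotency and inner cell mass, trophectoderm, primitive endoderm, glycolysis, antioxidant defence, heat shock and unfolded protein response, apoptosis, epigenetic regulators, imprinted genes, cholesterol and fatty acid metabolism, cell cycle, the insulin-like growth factor system, interferon response, ribosomal proteins, oxidative phosphorylation, proteasome, and spliceosome, with cumulus and granulosa cells, blood and sperm as other cell types. The lists, the model, the naming rule and the alternatives not marked otherwise were chosen before the data were examined. Each list was tested with limma's camera at a preset correlation of 0.01, on the probe set of highest mean for each of 9155 genes, with adjustment over the lists. Beside it stand camera with an estimated correlation, fry, which asks another question (whether a list changed at all, not whether it changed more than other genes), and the percentile of the list's median among 10000 random lists of matched level. Some lists overlap: genome activation and pluripotency share 3 genes, genome activation and heat shock 1, epigenetic regulators and pluripotency 1, imprinted genes and the insulin-like growth factor system 2, and cumulus cells and imprinted genes 1.

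The alternatives were quantile normalization, centring each array on its median, offsets of 1 and 64, leaving out the 40% of probe sets of lowest mean, a variance prior without a trend, array weights, a fit of only the groups compared, replicate number as a block, other calling rules, the mean of all probe sets of a gene, and leaving out each array in turn. A floor at the highest background, on 3367 probe sets, other limits for counting probe sets above background, that count without each array, and counts of called probe sets without each array of the groups not compared were added after seeing the data. The floor, 1664, is the background of prepubertal 8-16-cell replicate 3 and was applied to every array. In comparisons without that array it also covers signals that lay above their own array's background.

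The steps were tested on simulated data, with 200 of the 24016 probe sets changed, 50 at each size. The changed ones were drawn from probe sets with a mean above the median of all. Residuals were drawn for each probe set on its own over all arrays, so a dim array or a shift of a whole array was not simulated. The shares below hold for that setting. At a log2 change of 2 none was recovered (0%) in any of the 4 comparisons of groups. At 4 the share was 18% for the donor comparison at the 8-16-cell stage, 2% for that in blastocysts, and 10% and 4% for the stage comparison in the adult and prepubertal groups. At 6 these shares were 56%, 60%, 56% and 62%, at 8 they were 82%, 76%, 74% and 72%, and 8, 5, 1 and 5 unchanged probe sets were called. Scanner images, probe-level files and detection calls were not used here.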

Results

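The arrays profiled gene expression in embryos of Japanese Black cattle at 2 stages. Oocytes from abattoir ovaries of adult cows, or from ovaries of heifers aged 9 to 12 months, were matured and fertilized in vitro and grown in culture. The 8-16-cell embryos, in which the bovine embryonic genome takes over from stored maternal RNA, were taken on day 3, at 70 to 72 h after insemination, in pools of 50. Expanded blastocysts, which hold an outer trophectoderm and an inner cell mass, were taken on day 7 in pools of 10. Each donor group and stage had 3 arrays, each from its own pool (n = 3 throughout). Whether pools shared animals, a bull or a day of culture is not given in the sources used here, so p-values speak only for these pools. limma's p rests mostly on the spread of probe sets of like level. Its prior has 195.66 degrees of freedom against 8 residual, so a probe set's own spread between pools counts for little.

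The number of probe sets above background was 6435 ± 858 (SD, n = 3) in adult 8-16-cell embryos, 3628 ± 2120 in prepubertal 8-16-cell embryos, 6442 ± 495 in adult blastocysts and 8329 ± 187 in prepubertal blastocysts. The donor groups did not overlap at either stage: prepubertal minus adult was -2806 at the 8-16-cell stage and 1887 in blastocysts (exact permutation test, p = 0.1 each, the smallest possible). Without prepubertal 8-16-cell replicate 3 the first of these was -1620. The donor difference itself differed between stages by 4694 probe sets (exact permutation test, p = 0.005, the smallest possible of 400 permutations), and by 3507 without that array (p = 0.01). Above a fixed signal of 2000, a limit chosen after seeing the data, the donor differences were -425 and -78.7. The one in blastocysts thus turned, and the difference between stages was 347 and did not pass (exact permutation test, p = 0.315). Prepubertal 8-16-cell replicate 3 stood apart, with 1255 probe sets above background, a background of 1664 where the other arrays had 122 to 424, and 49.3% of its signal in its top 100 probe sets where the others had 23.3% to 32.7%. The hybridization controls, spiked in equal amount, read 3.03-fold higher in prepubertal than in adult 8-16-cell arrays (exact permutation test, p = 0.1) and 1.06-fold higher in blastocysts (p = 0.8). The median of all probe sets was likewise shifted, by 0.59 on the log2 scale for prepubertal against adult 8-16-cell embryos, 0.16 in blastocysts, and 0.08 and -0.37 for blastocyst against 8-16-cell in the adult and prepubertal groups. After quantile normalization these shifts were 0.05, -0.0014, -0.03 and -0.12. List medians are therefore given relative to the median of all genes. Along the first principal component (28.9% of the variance over 9807 probe sets) the 8-16-cell arrays lay between -123 and -78.8 and the blastocyst arrays between 93.6 and 107, and replicate 3 lay at -208 on the second (11.8%).

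**Figure D1:**
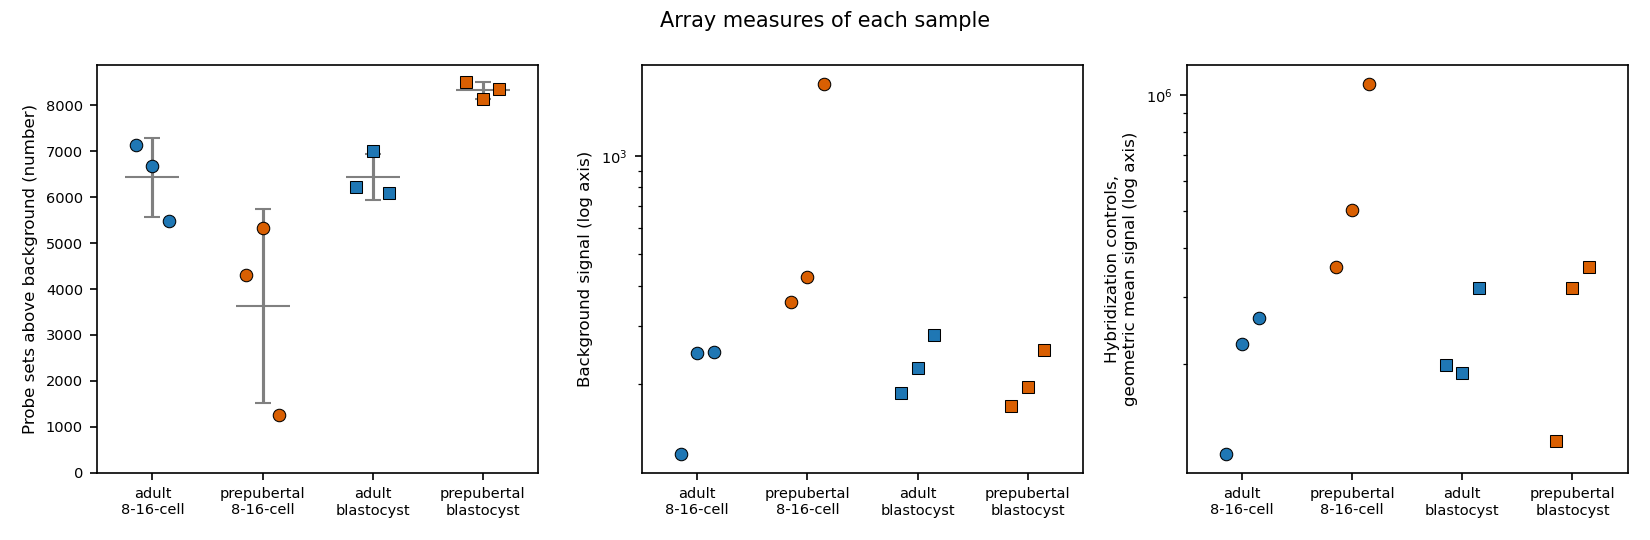
Probe sets above background, background signal and hybridization controls of each of the 12 arrays (blue adult, orange prepubertal; circles 8-16-cell, squares blastocyst), with the mean and SD (n = 3) in the first panel. Prepubertal 8-16-cell replicate 3 has the highest background (1664) and the fewest probe sets above it (1255).

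Blastocyst against 8-16-cell asks what changes as the embryo moves from genome activation to its first epithelium. In the adult group the named genes that rose were of several kinds. LGALS3, which encodes the lectin galectin-3, read 16.00 ± 0.75 (log2 signal, SD) in blastocysts and 6.34 ± 1.73 at the 8-16-cell stage, at least 307-fold higher (adjusted p = 9.97e-09). PDPN (podoplanin, a membrane glycoprotein) rose at least 168-fold, the matrix protein gene FN1 (fibronectin) at least 131-fold, KRT18 (a keratin of simple epithelia) at least 80.3-fold, and ZYX (zyxin, of focal adhesions) at least 68.1-fold. The protease gene PLAU (urokinase) rose at least 62.7-fold, PTGS2 (a prostaglandin synthase) at least 50.0-fold, SCP2 (a sterol carrier) at least 49.6-fold, NDUFS4 (a subunit of respiratory complex I) at least 48.1-fold, and TMEM184B at least 42.2-fold. Their adjusted p ran from 9.97e-09 to 5.7e-05.

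Transcripts of the oocyte were among the falls. GRO1, a chemokine gene, fell from 14.95 ± 0.34 to 5.58 ± 1.94, at least 130-fold lower in adult blastocysts (adjusted p = 2.99e-07). The oocyte growth factor gene BMP15 was at least 98.5-fold lower (adjusted p = 0.000104) and KPNA7, an importin of oocytes and early embryos, at least 56.4-fold lower (adjusted p = 2.13e-06). TECTB fell at least 49.3-fold, the transcription factor gene MYB at least 47.6-fold, MLLT11 at least 43.5-fold, FEM1C at least 43.2-fold, and FBXO34 at least 16.4-fold (adjusted p at most 0.00189). UHRF1, which maintains DNA methylation, changed by -7.32 (SE 1.43, adjusted p = 0.000315) and PAXBP1 by -7.03 (SE 1.24, adjusted p = 5.02e-05), each above background on 1 of 3 blastocyst arrays. With all signals floored at the highest background, TMEM184B (2.43, adjusted p = 0.0566) and FBXO34 (-1.26, adjusted p = 0.318) no longer passed. Over all alternatives the adjusted p of TMEM184B ran from 8.34e-07 to 0.0566 and that of FBXO34 from 0.000161 to 0.318.

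In all, limma called 512 probe sets in the adult group, 303 higher and 209 lower in blastocysts, at adjusted p 0.05. They included 185 named genes among the higher and 138 among the lower, and 171 probe sets with no gene name. On 252 of them the dimmer stage was at background on all 3 arrays. The 3 arrays of each stage did not overlap for 17.2% of probe sets, where chance gives 10%. The count fell to 292 without adult 8-16-cell replicate 3 and to 253, 285 and 274 without adult blastocyst replicates 1, 2 and 3, and array weights raised it to 889. It rose to 794 (473 higher, 321 lower) without prepubertal 8-16-cell replicate 3, which is not in this comparison but shares the variance of the fit.

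Of the fixed lists, trophectoderm, respiration and maternal transcripts changed in the adult group under camera and also with an estimated correlation. The floor at the highest background, set by an array outside this comparison, ended the call of maternal transcripts. Many members lay at background at one stage. Each called list's median is also given with those members at their bound, or at 0 where both stages were at background. The trophectoderm list, of genes of the outer epithelium, lay 2.45 above all genes (2.07 at bound, camera adjusted p = 3.01e-07, and adjusted p = 0.00775 with an estimated correlation): 7 of its 26 measured members rose, 1 fell and 18 did not pass. Adjusted over the list alone, 13 rose and 1 fell. Among them the tight-junction gene CLDN6 rose by 7.16 (SE 1.43, adjusted p = 0.000432), S100A14 rose at least 27.9-fold, and the sodium pump subunit gene ATP1B1 was the member that fell. Oxidative phosphorylation lay 2.22 above all genes (2.25 at bound, adjusted p = 1.29e-13, and adjusted p = 0.0415 with an estimated correlation), with 11 of 80 higher and none lower (27 and 0 adjusted over the list alone). NDUFB6 of complex I rose at least 24.6-fold, COX5B of cytochrome c oxidase rose by 6.77 (SE 1.31), and SDHC of complex II by 5.12 (SE 1.11). Maternal and oocyte transcripts lay at -1.61 (-0.92 at bound, adjusted p = 0.00024, and adjusted p = 0.0425 with an estimated correlation), with KPNA7 and BMP15 the 2 of 14 that fell (4 adjusted over the list alone). With all signals floored at the highest background the list lay at -0.083 and was not called (adjusted p = 0.142, with 3.68e-05 to 0.142 over all alternatives).

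Another 9 lists passed camera in the adult group but not with an estimated correlation. Ribosomal proteins lay 1.61 above all genes (1.65 at bound, adjusted p = 7.12e-08, and adjusted p = 0.0807 with an estimated correlation), although 2 of 67 members rose and 2 fell (6 and 2 adjusted over the list alone): RPS3 rose by 2.99 (SE 0.86) and RPS4Y1 by 3.30 (SE 0.97), while RPL21 fell by 5.91 (SE 1.15) and RPS19 fell at least 5.83-fold. Cell cycle genes lay at -1.41 (-1.12 at bound, adjusted p = 0.00355, and adjusted p = 0.0591 with an estimated correlation). The mitotic kinase gene AURKA fell by 6.21 (SE 0.71, adjusted p = 2.22e-11) and the spindle checkpoint gene BUB3 by 2.87 (SE 0.80), as 2 of 37 members (1 rose and 3 fell adjusted over the list alone). Heat shock genes lay at 1.31 (1.45 at bound, adjusted p = 0.0111, and adjusted p = 0.103 with an estimated correlation). The mitochondrial chaperone gene HSPD1 rose by 4.16 (SE 0.99), HSPA1A fell by 4.27 (SE 1.19), and 26 of 28 did not pass (9 rose and 2 fell adjusted over the list alone). Antioxidant genes lay at 1.24 (0 at bound, adjusted p = 0.0402, and adjusted p = 0.136 with an estimated correlation), with PRDX2 up by 6.68 (SE 1.39), IDH1 by 5.59 (SE 1.26) and PRDX1 by 4.13 (SE 1.13), while PRDX6 fell by 3.36 (SE 0.99). Of 29, 4 rose and 1 fell adjusted over the list alone.

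Glycolysis lay at 1.04 (0.73 at bound, adjusted p = 0.014, and adjusted p = 0.0591 with an estimated correlation), where the fructose transporter gene SLC2A5 rose by 6.16 (SE 1.45) as 1 of 26 members (2 adjusted over the list alone). Cholesterol and fatty acid metabolism lay at 0.79 (0.80 at bound, adjusted p = 0.0158, and adjusted p = 0.0591 with an estimated correlation), with ACSL3 at least 37.2-fold and SCD at least 6.72-fold higher as 2 of 31 (4 adjusted over the list alone). Primitive endoderm lay at 0.74 (0 at bound, adjusted p = 0.0242, and adjusted p = 0.128 with an estimated correlation), where FN1 was the 1 of 17 that rose (1 adjusted over the list alone). The proteasome lay at 1.26 (0.99 at bound, adjusted p = 0.0379, and adjusted p = 0.136 with an estimated correlation), with PSMD4 up by 4.87 (SE 1.45) and PSMD9 down, at -4.94 (SE 1.46), and the remaining 27 of 29 not passing (1 and 1 adjusted over the list alone). The spliceosome lay at -0.57 (-0.39 at bound, adjusted p = 0.0321, and adjusted p = 0.128 with an estimated correlation), and none of its 52 members passed (0 adjusted over the list alone). Among random lists of matched level the spliceosome lay at percentile 10.7, primitive endoderm at 95.1 and cholesterol at 95.6, so some lists of like level moved as far. CLDN6, PRDX2, SLC2A5, PSMD4 and PSMD9 had 1 of 3 arrays of the dimmer stage above background, so their sizes rest in part on background. The floor at the highest background ended the calls of primitive endoderm (0.69), glycolysis (0.25), antioxidant (0.41), cholesterol (0.36), proteasome (0.33) and spliceosome (-0.73). Single arrays ended some as well. Primitive endoderm was lost without adult 8-16-cell replicate 2 (adjusted p = 0.0843), and antioxidant without adult 8-16-cell replicates 1 and 2 or adult blastocyst replicate 3 (0.0512, 0.141 and 0.107). The proteasome was lost without adult 8-16-cell replicate 1 or adult blastocyst replicates 1 and 3 (0.0698, 0.0518 and 0.0876), and spliceosome without adult 8-16-cell replicates 1 and 3 or adult blastocyst replicate 3 (0.14, 0.0688 and 0.0849). Over all alternatives their adjusted p ran from 0.00422 to 0.128, 0.00833 to 0.286, 0.00849 to 0.302 and 0.0119 to 0.334. The 0.334 is from fry, which asks whether a list changed at all.

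The other 10 lists were not called in the adult group. Embryonic genome activation lay at -0.70 (adjusted p = 0.22), with HSPA1A the 1 of 11 members that fell. Pluripotency lay at 1.74 (adjusted p = 0.483), with the de novo DNA methyltransferase gene DNMT3B, at least 15.0-fold higher, the 1 of 6 that rose. Epigenetic regulators lay at -0.13 (adjusted p = 0.986), with DNMT3B higher and UHRF1 lower of 26. Apoptosis lay at 0.26, with a mean and a camera direction below 0 (adjusted p = 0.704), and the stress gene GADD45A fell by 3.72 (SE 1.09) as 1 of 19 members. No member passed among the 23 imprinted genes (0.31, adjusted p = 0.972), the 19 genes of the insulin-like growth factor system (-0.07, with camera's direction up, adjusted p = 0.986), and the 17 of the interferon response (0.27, adjusted p = 0.8). The same held for cumulus and granulosa cells (0.11, with camera's direction down, adjusted p = 0.986, 27 members of which 11 were at background on all arrays), blood (-0.82, adjusted p = 0.325, 15 members) and sperm (-0.36, adjusted p = 0.696, 8 members).

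**Figure D2:**
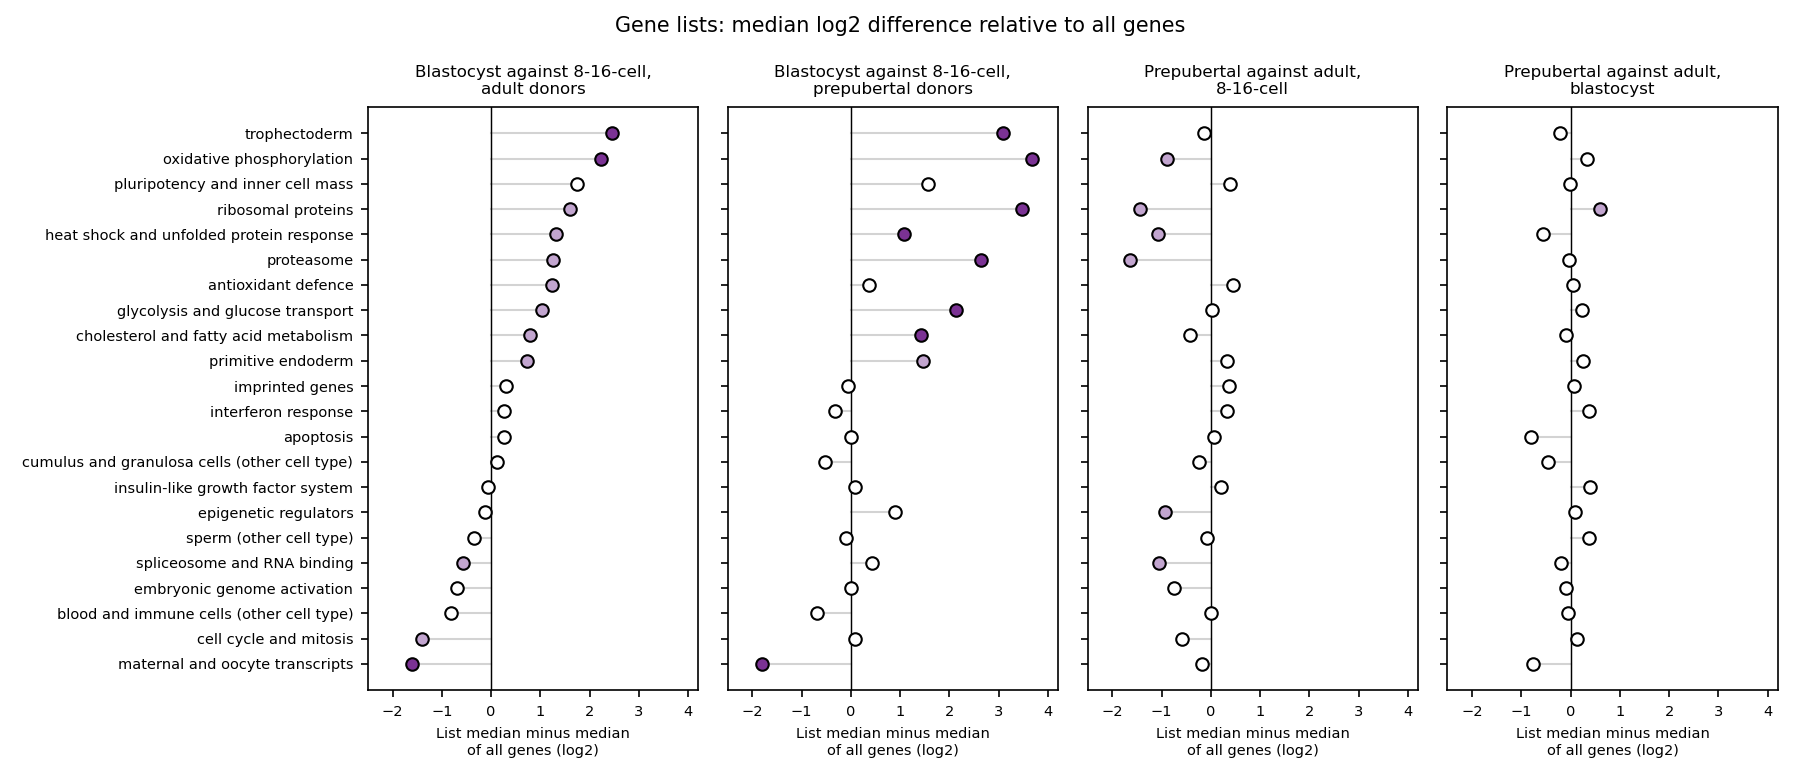
Median log2 difference of each of the 22 gene lists relative to all genes in the 4 comparisons of groups. Dark points passed camera and camera with an estimated correlation, light points passed camera alone and white points passed neither; trophectoderm lies at 2.45 and 3.09 in the adult and prepubertal stage comparisons (2.07 and 0.29 with members at background at their bound), and maternal transcripts at -1.61 and -1.81 (-0.92 and -0.47).

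In the prepubertal group the rises from the 8-16-cell stage to the blastocyst included the same lectin gene and subunits of the respiratory chain. LGALS3 went from 6.59 ± 1.14 to 16.20 ± 0.60 (log2 signal, SD), at least 116-fold higher (adjusted p = 7.51e-09). COX5B and COX5A of cytochrome c oxidase rose at least 53.6-fold (adjusted p = 7.01e-07) and at least 23.0-fold (adjusted p = 4.08e-06). The lysosomal gene PSAP rose by 8.18 (SE 1.07, adjusted p = 4.92e-09) and PDPN by 8.17 (SE 1.35, adjusted p = 6.59e-06), each with 1 of 3 dim arrays above background. The actin-binding genes TPM4 and PLS1 rose at least 32.0-fold and 14.8-fold, TMEM258 at least 13.4-fold, TSPAN6 at least 10.9-fold, and DNMT3A, a de novo DNA methyltransferase, at least 9.00-fold (adjusted p at most 0.000213).

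GRO1 fell from 16.11 ± 1.68 to 6.25 ± 1.62 in the prepubertal group, at least 321-fold lower (adjusted p = 2.55e-08), and BMP15 fell at least 58.8-fold (adjusted p = 2.09e-06). KPNA7 fell by 9.00 (SE 1.38, adjusted p = 1.13e-06), ZNF668 by 8.64 (SE 1.38), the coactivator gene PNRC1 by 8.32 (SE 1.39), the corepressor gene TBL1XR1 by 7.36 (SE 1.40) and the chromatin protein gene HMGN4 by 7.08 (SE 1.16). The blastocyst group of the first 4 was above background on 1 of 3 arrays, so these sizes rest in part on background. SVIL, which binds actin, fell at least 89.6-fold, ATF7IP at least 44.4-fold and the junction gene JAM2 at least 22.9-fold (adjusted p = 0.00167). JAM2 was above background on 2 of 3 arrays at the 8-16-cell stage. It was lost without prepubertal 8-16-cell replicate 3 (at least 4.82-fold, adjusted p = 0.105) and with all signals floored at the highest background (-2.54, adjusted p = 0.107), with 0.000104 to 0.107 over all alternatives.

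The prepubertal group had 563 called probe sets, 344 higher and 219 lower in blastocysts, covering 250 and 134 named genes and 158 probe sets with no name. On 273 of them the dimmer stage was at background on all 3 arrays, and 16.6% of probe sets did not overlap between stages, where chance gives 10%. The count was 299, 272 and 273 without prepubertal blastocyst replicates 1, 2 and 3, and 535 without prepubertal 8-16-cell replicate 3, of which 393 were shared with the 563.

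Lists for protein synthesis and respiration were higher in the blastocysts of the prepubertal group, against 8-16-cell arrays of which replicate 3 stands apart and whose hybridization controls were 3.03-fold those of the adult group. Ribosomal proteins lay 3.47 above all genes (3.15 at bound, camera adjusted p = 3.11e-33, and adjusted p = 0.00476 with an estimated correlation), with 27 of 67 members higher, none lower and 40 not passing (56 higher and 1 lower adjusted over the list alone). RPL14 rose by 7.33 (SE 1.32), RPS15 by 7.13 (SE 1.28), RPL27A by 6.06 (SE 1.10) and RPS18 by 4.81 (SE 0.82). Oxidative phosphorylation lay at 3.69 (2.20 with 49 of 80 members at their bound or at 0, adjusted p = 1.43e-27, and adjusted p = 0.00476 with an estimated correlation), with 29 of 80 higher, none lower and 51 not passing (50 higher and 1 lower adjusted over the list alone). Among them were ATP5F1A of ATP synthase, up by 6.0 (SE 1.02) on its brighter probe set, and COX7A2, up by 5.61 (SE 0.97). Trophectoderm lay at 3.09, but at 0.29 with the 20 of 26 members at background at their bound or at 0 (adjusted p = 2.47e-05, and adjusted p = 0.0082 with an estimated correlation): 8 of 26 rose and none fell (14 and 2 adjusted over the list alone), with CLDN6 at least 28.6-fold, S100A14 at least 14.7-fold and PTGS2 at least 9.73-fold higher. The proteasome lay at 2.63 (1.73 at bound, adjusted p = 6.17e-07, and adjusted p = 0.0086 with an estimated correlation), where 4 of 29 rose (12 adjusted over the list alone), including PSMA5, up by 4.47 (SE 1.30).

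Maternal transcripts lay at -1.81 (-0.47 at bound, adjusted p = 0.000208, and adjusted p = 0.0187 with an estimated correlation): KPNA7, BMP15 and the zona pellucida gene ZP4, at least 9.79-fold lower, were the 3 of 14 that fell (5 adjusted over the list alone). Heat shock genes lay at 1.08 (0.78 at bound, adjusted p = 0.000526, and adjusted p = 0.0351 with an estimated correlation), with 5 of 28 higher (9 higher and 1 lower adjusted over the list alone), though at percentile 82.5 of random lists of matched level. The chaperone genes CANX, HSPD1 and HSPE1 rose by 6.27 (SE 1.02), 4.62 (SE 0.99) and 4.28 (SE 1.08). Glycolysis lay at 2.13 (0.47 at bound, adjusted p = 0.00117, and adjusted p = 0.0179 with an estimated correlation), with GAPDH at least 3.40-fold and ALDOA at least 4.19-fold higher as 2 of 26 (8 higher and 1 lower adjusted over the list alone). Cholesterol and fatty acid metabolism lay at 1.43 (0 at bound, adjusted p = 0.00211, and adjusted p = 0.0182 with an estimated correlation), with the elongase gene ELOVL6 at least 10.9-fold and the desaturase gene FADS2 at least 3.56-fold higher as 2 of 31 (5 adjusted over the list alone). Primitive endoderm lay at 1.46 (0 at bound, adjusted p = 0.00955, and adjusted p = 0.0946 with an estimated correlation), where FN1, at least 40.8-fold higher, was the 1 of 17 that rose (2 adjusted over the list alone). The floor at the highest background ended 5 of the 9 calls: the proteasome (0.66, adjusted p = 0.0664), heat shock (0.77, 0.132), glycolysis (0.91, 0.0986), cholesterol (0.21, 0.439) and primitive endoderm (1.11, 0.095). Each of these was the highest adjusted p of that list over all alternatives, and the lowest ran from 1.04e-08 for the proteasome to 0.00196 for primitive endoderm. RPL14, RPS15, ATP5F1A, PSMA5, and IDH1, TXN, PRDX1 and KLF5 below, were above background on 1 of 3 arrays at the 8-16-cell stage.

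The remaining 13 lists were not called in the prepubertal group. Antioxidant genes lay at 0.36 (adjusted p = 0.151), with IDH1 up by 6.70 (SE 1.26), TXN by 4.57 (SE 1.23) and PRDX1 by 4.10 (SE 1.13), and PRDX6 down, at -4.12 (SE 0.99). Cell cycle genes lay at 0.09, with camera's direction down (adjusted p = 0.522), and AURKA fell by 4.33 (SE 0.71, adjusted p = 6.01e-06) as 1 of 37. The pluripotency genes KLF5 and KLF4 went opposite ways, by 5.07 (SE 1.29) and -3.28 (SE 0.56), in a list that lay at 1.56 (adjusted p = 0.734) and in that of genome activation (-0.01, adjusted p = 0.678). Apoptosis lay at -0.01 (adjusted p = 0.656), where GADD45A fell by 4.36 (SE 1.09) and DIABLO by 3.52 (SE 0.79). The histone-modifying enzyme genes KDM1A and HDAC1 rose at least 11.2-fold and 6.71-fold in a list of epigenetic regulators that lay at 0.89 (adjusted p = 0.122). XIST, the RNA that silences an X chromosome, rose at least 4.62-fold among imprinted genes (-0.06, adjusted p = 0.813). The spliceosome lay at 0.44 (adjusted p = 0.678), with SF3A2 at least 4.76-fold higher and HNRNPDL and SRSF3 lower by -2.60 (SE 0.69) and -2.62 (SE 0.72). STAR, a gene of steroid synthesis, fell at least 13.4-fold in the cumulus and granulosa list (-0.54, adjusted p = 0.558), and ODF2 rose at least 4.09-fold in the sperm list (-0.10, adjusted p = 0.861). No member passed for the insulin-like growth factor system (0.08, adjusted p = 0.918), interferon response (-0.32, adjusted p = 0.558) or blood (-0.70, adjusted p = 0.122).

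Lists called in only the adult group did not differ between donor groups past the threshold with an estimated correlation: the difference was 1.05 for cell cycle (camera adjusted p = 0.0924), -0.04 for antioxidant genes (adjusted p = 0.765) and 0.81 for the spliceosome (adjusted p = 0.0195, and adjusted p = 0.2 with an estimated correlation).

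The stage change called the same probe sets in both donor groups far more often than independent calls would. Of the higher ones 118 were called in both, where independence gives 4.34 (Fisher's exact test, p = 3.15e-142), and of the lower ones 69, where it gives 1.91 (p = 1.02e-90). These groups share no array, and none was called in opposite directions. Both comparisons take the variance of a probe set from the same fit, and probe sets at background throughout can hardly be called in either. This raises the overlap above independence by itself, so Fisher's p is not a test of a shared change alone. LGALS3, PDPN, GRO1, BMP15 and KPNA7 were among the named genes called in both. Over the 9807 probe sets above background on 3 or more arrays the stage differences of the donor groups correlated across probe sets with r = 0.59 and rho = 0.55, although probe sets are not independent replicates. Over all 24016 probe sets, those at background included, r was 0.45 and rho 0.32, and 58.4% had the same direction.

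Stage markers showed the same contrast in part. KRT18 read 14.06 ± 0.55 and 14.52 ± 0.68 in adult and prepubertal blastocysts against 5.98 ± 1.70 and 7.94 ± 0.93 at the 8-16-cell stage, a rise of 6.58 (SE 1.36, adjusted p = 0.000602) in the prepubertal group, where 1 of 3 8-16-cell arrays was above background. BMP15 read 14.55 ± 0.29 and 13.66 ± 1.22 at the 8-16-cell stage and was at background on all 6 blastocyst arrays. POU5F1, the gene of a pluripotency factor, read 6.41 ± 1.23 and 7.91 ± 2.05 at the 8-16-cell stage and 9.77 ± 1.29 and 10.52 ± 0.99 in blastocysts, without passing (adjusted p = 0.315 and 0.444). The trophoblast interferon gene IFNT2 read 10.71 ± 2.55 and 8.96 ± 3.48 in blastocysts and did not pass either (adjusted p = 0.0597 and 0.27). GDF9, another oocyte growth factor gene, read 9.34 ± 1.15 and 9.50 ± 2.47 at the 8-16-cell stage (adjusted p = 0.451 and 0.184), and NLRP5 was above background on 1 of the 12 arrays. None of these markers passed between donor groups at either stage, with adjusted p from 0.674 to 1.

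**Figure D3:**
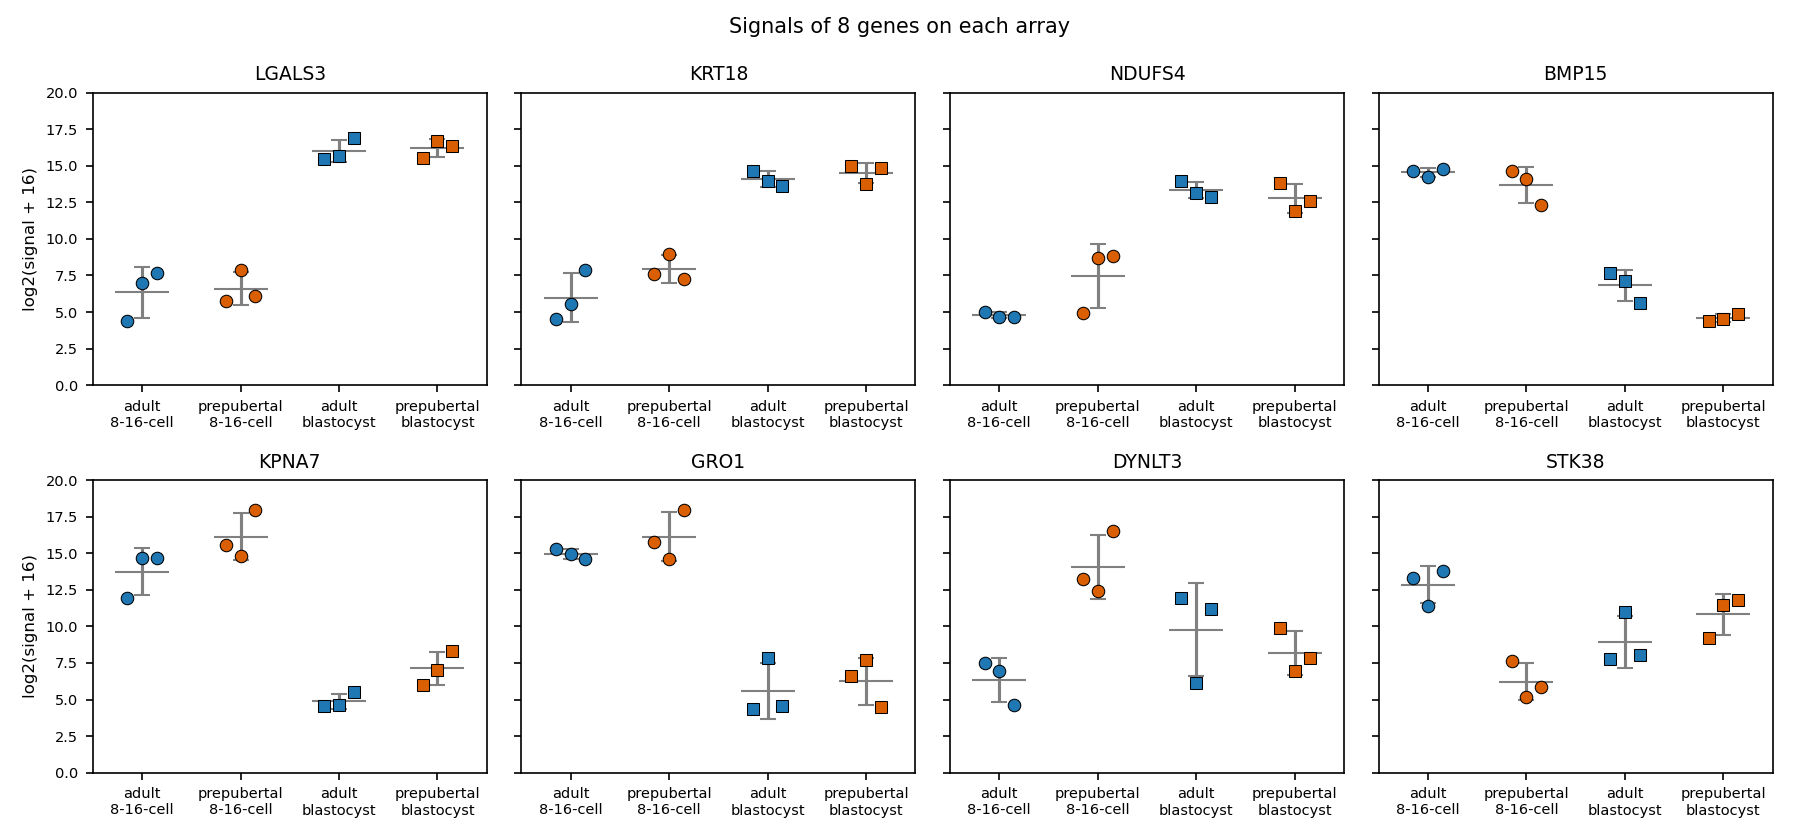
Log2 signal of 8 genes on each array, with the mean and SD (n = 3) of each group; circles are 8-16-cell embryos and squares blastocysts. LGALS3, KRT18 and NDUFS4 are higher in blastocysts, BMP15, KPNA7 and GRO1 at the 8-16-cell stage, and DYNLT3 and STK38 part the donor groups at the 8-16-cell stage.

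Prepubertal against adult asks how the age of the oocyte donor marks the embryo's transcripts. At the 8-16-cell stage 5 probe sets passed. DYNLT3, a light chain of the dynein motor, read 14.06 ± 2.16 in prepubertal and 6.36 ± 1.5 in adult embryos, a difference of 7.70 (SE 1.48, adjusted p = 0.00549) with 1 of 3 adult arrays above background. STK38, a kinase of the Hippo family, read 12.83 ± 1.26 in adult and 6.23 ± 1.26 in prepubertal embryos, at least 11.2-fold lower (adjusted p = 0.0419). The other 3 have no gene name and were chosen after their values were seen: one read 13.83 ± 6.19 in prepubertal embryos and was at least 68.2-fold higher (adjusted p = 9.81e-05), another was at least 7.33-fold higher (adjusted p = 0.0412), each above background on 2 of 3 prepubertal arrays, and the last fell by 5.50 (SE 1.17, adjusted p = 0.0393).

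Each of these calls was lost under several alternatives, some of which left out no array. With a variance prior without a trend none of the 5 passed, although the sizes stayed as they were. DYNLT3 did not pass without adult 8-16-cell replicate 3 (6.85, adjusted p = 0.0693) or prepubertal 8-16-cell replicate 3 (6.48, adjusted p = 0.128). With all signals floored at the highest background it was 3.36 (adjusted p = 0.275; 0.00555 to 0.275 over all alternatives), and its other 2 probe sets did not pass. STK38 did not pass without adult 8-16-cell replicate 1 (-6.36, adjusted p = 0.366), adult replicate 3 (-6.13, 0.194), prepubertal replicate 2 (-6.09, 0.0982) or prepubertal replicate 3 (-6.41, 0.0725). It was also lost, at nearly the same size, with array weights (-6.63, 0.0568) or a replicate block (-6.60, 0.0712), and with the floor at the highest background it was -2.12 (0.406). Its adjusted p ran from 0.0162 to 0.406 over all alternatives. Of the unnamed probe sets, the 68.2-fold one did not pass without prepubertal replicate 3, where its bound fell to 7.20-fold and its fitted difference from 9.24 to 6.0 (adjusted p = 0.0725; 1.66e-07 to 0.0725 over all alternatives). The 7.33-fold one was lost without adult replicate 1, 2 or 3 (5.93, 6.04 and 5.89, against 5.96 with all arrays; adjusted p = 0.366, 0.15 and 0.154; 0.0286 to 0.406 over all alternatives). The one that fell was lost likewise (-5.30, -5.86 and -5.33; adjusted p = 0.366, 0.0655 and 0.147; 0.0162 to 0.366), and with the floor (-3.91, 0.159). The count of 5 (3 higher, 2 lower) became 2 without adult 8-16-cell replicate 1, 9 without prepubertal replicate 1 and 14 without prepubertal replicate 2. It also became 2 (2 higher, 0 lower) without adult blastocyst replicate 2 or prepubertal blastocyst replicate 1, 2 or 3, which share the variance of the fit. Median-centred arrays gave 17 (3 higher, 14 lower) and quantile normalization 8 (3 higher, 5 lower). At an unadjusted p under 0.05 there were 2166 probe sets (9.02%, 1671 higher and 495 lower), and the groups did not overlap for 12.7%, where chance gives 10%.

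The genes that came closest on the lower side did not pass. SGK1, a stress-induced kinase, differed by -4.57 (SE 1.07, adjusted p = 0.082), COX7A2 by -4.02 (SE 0.97, adjusted p = 0.11), the chaperone gene CANX by -4.15 (SE 1.02, adjusted p = 0.134) and RPL27A by -4.40 (SE 1.10, adjusted p = 0.137). The proton pump gene ATP6V1A was at least 5.36-fold lower (adjusted p = 0.082), the nucleolar gene GNL3 at least 6.95-fold (adjusted p = 0.0924), the chromatin remodeller gene SMARCA4 at least 10.7-fold (adjusted p = 0.137), NOP9 at least 2.05-fold (adjusted p = 0.16) and IBTK at least 7.83-fold (adjusted p = 0.239). Centring passed all of these but IBTK, SGK1 among them at adjusted p = 0.03, and quantile normalization passed SGK1 (0.0286), ATP6V1A (0.0242) and COX7A2 (0.0444). Leaving out single arrays also passed some of them: ATP6V1A without adult replicate 3 (0.00211), COX7A2 without prepubertal replicate 3 (0.0278), and SGK1 (0.0489), CANX (0.0439) and RPL27A (0.0439) without prepubertal replicate 2, as with CASKIN2 on the higher side (0.0439). The floor at the highest background passed SGK1 too (-4.14, 0.0151). The highest adjusted p over all alternatives was 0.464 for SGK1, 0.682 for GNL3 and 0.712 for each of the others whose call changed. The other 2 probe sets of SGK1 lay on the other side. ADPRM, CASKIN2, ZNRD2, ATP5F1A, RABGAP1L, DEDD, GLYAT, EGFL8 and SLC22A5 came closest on the higher side (adjusted p from 0.231 to 0.272), all at background on every adult 8-16-cell array. ATP5F1A, GLYAT and SLC22A5 were at background on every prepubertal 8-16-cell array as well, so they were read in neither group. The other probe set of ATP5F1A, which stands for the gene in the lists, differed by -3.15 (SE 1.02, adjusted p = 0.369).

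Under camera 6 lists read lower than other genes in prepubertal 8-16-cell embryos, though none of their members passed over all genes and no call held with an estimated correlation. Among random lists of matched level the ribosomal list lay at percentile 0.11 and the proteasome at 0.48. Oxidative phosphorylation lay at 5.03, the spliceosome at 5.59, epigenetic regulators at 5.73 and heat shock at 18.6. Each percentile is the share of random lists of like level that read as low or lower. Ribosomal proteins lay at -1.44 relative to all genes (adjusted p = 1.38e-09, and adjusted p = 0.0977 with an estimated correlation). RPL27A, RPS15 at -4.45 (SE 1.28) and RPS3A at -2.90 (SE 0.94) passed when adjusted over the list alone (3 of 67). The proteasome lay at -1.64 (adjusted p = 5.56e-05, and adjusted p = 0.0781 with an estimated correlation), with PSMA5 at -3.6 (SE 1.30) and PSMA7 at -2.88 (SE 1.13), and the spliceosome at -1.04 (adjusted p = 0.000763, and adjusted p = 0.0781 with an estimated correlation), with SNRPC at -3.03 (SE 1.16). Neither had a member that passed adjusted over the list alone (0 of 29 and 0 of 52). Oxidative phosphorylation lay at -0.88 (adjusted p = 0.000936, and adjusted p = 0.287 with an estimated correlation), where 5 of 80, COX7A2 and NDUFB3 at -4.07 (SE 1.18) among them, were lower adjusted over the list alone. Heat shock genes lay at -1.07 (adjusted p = 0.00582, and adjusted p = 0.12 with an estimated correlation), with CANX lower and PDIA4 higher adjusted over the list alone, and epigenetic regulators at -0.94 (adjusted p = 0.0287, and adjusted p = 0.0977 with an estimated correlation), with SMARCA4 the 1 lower. RPS15, PSMA5 and NDUFB3 were above background on 1 of 3 prepubertal arrays.

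These arrays also differ in quality by donor group, with hybridization controls 3.03-fold higher in the prepubertal 8-16-cell group and a difference of -2806 in probe sets above background (-1620 without prepubertal 8-16-cell replicate 3). Without prepubertal 8-16-cell replicate 3 the calls of the spliceosome (-0.39, adjusted p = 0.258), heat shock (-0.24, adjusted p = 0.683) and epigenetic regulators (-0.37, adjusted p = 0.295) were lost, and that of ribosomal proteins stood (-0.93, adjusted p = 2.05e-07). The call of epigenetic regulators also ended without adult 8-16-cell replicate 2 (0.0884) or prepubertal 8-16-cell replicate 2 (0.0731). Over all alternatives the adjusted p ran from 8.37e-05 to 0.753 for the spliceosome, 0.000773 to 0.963 for heat shock, 0.0124 to 0.295 for epigenetic regulators and 1.47e-14 to 0.239 for ribosomal proteins. The 0.239 is from fry, which asks whether the list changed at all, while camera with an estimated correlation gave 0.0977. With members at background set to their bound the ribosomal list lay at -0.86, the proteasome at -1.02, the spliceosome at -0.48 and heat shock at -0.28, while oxidative phosphorylation and epigenetic regulators lay at 0. With all signals floored at the highest background no list was called (0 of 22). The other 16 lists had adjusted p from 0.136 to 0.981: cell cycle lay at -0.58 and trophectoderm at -0.13, and among the other cell types cumulus and granulosa genes lay at -0.24, blood at 0.01 and sperm at -0.07.

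In blastocysts no probe set passed between donor groups. limma gave 0 of 24016 (smallest adjusted p = 0.797), with 884 (3.68%, 583 higher and 301 lower) at an unadjusted p under 0.05, and the groups did not overlap for 9.82%, where chance gives 10%. The actin-binding gene CORO2A was at least 32.9-fold higher in prepubertal blastocysts (adjusted p = 0.797), GART, an enzyme of purine synthesis, at least 11.3-fold (adjusted p = 0.797), POGZ at least 5.04-fold (adjusted p = 0.797) and MED4, of the Mediator complex, at least 3.41-fold (adjusted p = 1). AURKA differed by 2.68 (SE 0.71, adjusted p = 0.797), above background on all 6 arrays, and was the 1 cell cycle gene that passed adjusted over the list alone. The homeobox gene MSX1 differed by 3.6 (SE 1.12), and AKAP8, VPS26C, NSMCE1 and UXT were at least 4.24-fold, 3.69-fold, 2.72-fold and 2.53-fold higher (adjusted p = 1 each). On the lower side TBL1XR1, above background on 1 of 3 prepubertal arrays, differed by -4.29 (SE 1.40), TRIB2 by -4.28 (SE 1.5) and the helicase gene DHX9 by -2.11 (SE 0.76), and SNX6, NEBL and ZNF181 were at least 3.34-fold, 2.17-fold and 1.77-fold lower, with FRRS1, UBA6 and IL7 closer to background (adjusted p = 1 each). PRKCA was at background on every array of both groups and so was read in neither. A fit of only these 2 groups called 2 probe sets, CORO2A (adjusted p = 0.0428, with 0.0428 to 1 over all alternatives) among them.

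Ribosomal proteins were the 1 list of 22 called between donor groups in blastocysts, 0.59 higher in the prepubertal group (camera adjusted p = 0.00209, and adjusted p = 0.94 with an estimated correlation). None of 67 members passed, over all genes or adjusted over the list alone, and the call ended without prepubertal blastocyst replicate 1 (0.43, adjusted p = 0.185; 3.33e-09 to 0.94 over all alternatives). With members at background at their bound it lay at 0.75. RPL21 differed by 2.87 (SE 1.15) and RPS2 by 3.28 (SE 1.43). The other 21 lists had adjusted p from 0.353 to 0.994, with trophectoderm at -0.22, pluripotency at -0.01 and maternal transcripts at -0.77.

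The donor effect in blastocysts minus that at the 8-16-cell stage tests whether donor age acts alike at both stages. limma called 0 probe sets (smallest adjusted p = 0.241), with 1307 at an unadjusted p under 0.05 (422 higher and 885 lower). DYNLT3, higher in prepubertal 8-16-cell embryos, differed between stages by -9.27 (SE 2.09, adjusted p = 0.241) and passed without adult blastocyst replicate 2 (-11.08, adjusted p = 0.0174; 0.0174 to 0.895 over all alternatives). STK38 differed by 8.52 (SE 2.05, adjusted p = 0.251), SF3A2 by 8.93 (SE 2.16, adjusted p = 0.251), GART by 8.03 (SE 2.01, adjusted p = 0.271) and the mitochondrial gene FASTKD2 by 7.45 (SE 1.98, adjusted p = 0.575). The donor effects of the stages were nearly unrelated across 9807 probe sets (r = 0.02, rho = 0.03).

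Of the lists, 4 differed between stages under camera, each less low or higher in prepubertal blastocysts than at the 8-16-cell stage, and none with an estimated correlation. The difference was 1.81 for ribosomal proteins (adjusted p = 6.69e-13, and adjusted p = 0.158 with an estimated correlation), 1.48 for oxidative phosphorylation (adjusted p = 0.000289, and adjusted p = 0.256 with an estimated correlation), 1.76 for the proteasome (adjusted p = 0.00491, and adjusted p = 0.195 with an estimated correlation) and 0.81 for the spliceosome (adjusted p = 0.0195, and adjusted p = 0.2 with an estimated correlation). The spliceosome lay at percentile 86.7 of random lists of matched level. SF3A2 was the 1 spliceosome member that passed adjusted over the list alone. The proteasome was lost without prepubertal blastocyst replicate 1 (1.48, adjusted p = 0.051; 0.00117 to 0.38 over all alternatives). The spliceosome was lost without adult 8-16-cell replicate 1 (0.29, adjusted p = 0.11) or 3 (0.79, 0.0647), prepubertal 8-16-cell replicate 3 (0.43, 0.643), adult blastocyst replicate 3 (0.49, 0.0536) or prepubertal blastocyst replicate 1 (0.55, 0.15), with 0.00398 to 0.686 over all alternatives. Heat shock genes (0.52, adjusted p = 0.596) and epigenetic regulators (0.73, adjusted p = 0.17), called at the 8-16-cell stage alone, did not differ past the threshold.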

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

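The tests of level-matched lists, of shared variation (the estimated correlation had been chosen in advance for the lists, but not for this use), of labelled cDNA, of another stage and of brightness were chosen after the results were seen. Those of a dim array and of pool size were planned, but the first names a list and an array that the results had already shown.

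For 5 results the effect of the donor differed between stages by a test of the difference itself. By camera with the preset correlation, the donor effect in blastocysts minus that at the 8-16-cell stage was 1.81 for ribosomal proteins (adjusted p = 6.69e-13), 1.48 for oxidative phosphorylation (0.000289), 1.76 for the proteasome (0.00491) and 0.81 for the spliceosome (0.0195), as medians relative to all genes. With an estimated correlation none of these passed (0.158, 0.256, 0.195 and 0.2). For probe sets above background the difference was 4694 (exact permutation test, p = 0.005, the smallest that 400 permutations give), but above a fixed signal of 2000, chosen after seeing the data, it was 347 (p = 0.315), with donor differences of -425 at the 8-16-cell stage and -78.7 in blastocysts.

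The first pattern weighed is the lower signal of ribosomal protein genes in prepubertal 8-16-cell embryos. One dim array as the whole cause is argued against: without prepubertal 8-16-cell replicate 3 the list median was -0.93 (adjusted p = 2.05e-07). A lower reading of all abundant genes is argued against for this list, since its median lay at percentile 0.11 of random lists of matched level (0.01 without that array), but of the other lists called lower only the proteasome lay as far out (0.48), with oxidative phosphorylation, spliceosome, epigenetic regulators and heat shock at 5.03, 5.59, 5.73 and 18.6. Genes that vary together within groups stay open: with an estimated correlation the adjusted p was 0.0977 (0.0151 unadjusted), and the bound first written was for the unadjusted p, which the adjusted one replaced after both had been seen. A donor difference stays open and untested, and the hybridization controls, 3.03-fold higher in the same arrays, keep labelling open.

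The second is prepubertal 8-16-cell replicate 3, which stands apart from the other arrays. An array of the other stage is argued against, because over 569 probe sets above background on all arrays its mean correlation was 0.52 with 8-16-cell arrays and 0.30 with blastocyst arrays. Little labelled embryo cDNA stays open. The array had 1255 probe sets above background, where the lowest of the other arrays had 4297, but this count is part of what set it apart. The count is also taken over the array's own high background, so it cannot decide. Whether the embryos of that pool differed was not tested.

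The third is the change between stages. A difference in overall brightness is argued against, since maternal transcripts lay at -1.61 and -1.81 and trophectoderm at 2.45 and 3.09 relative to all genes in the adult and prepubertal groups. With members at background at their bound these were -0.92 and -0.47, and 2.07 and 0.29, so little is left of the argument in the prepubertal group, and with all signals floored at the highest background the adult maternal list lay at -0.083 and was not called. That floor is set by an array outside the adult group and lies above the background of every adult array. Stage cannot be told apart from pool size or array series, because the stages share 0 pool sizes (50 embryos against 10) and no range of array numbers. Development itself stays open.

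For each comparison of 3 arrays with 3, the 10 splits are too few for a share under 0.05. Between donor groups at the 8-16-cell stage 3 of 10 splits called as many probe sets as the real one (5), and the highest other called 13, with adult replicates 1 and 2 and prepubertal replicate 2 against the rest; what these arrays share was not tested, and the other splits called 0 to 5. In blastocysts the real split called 0 with limma (884 at an unadjusted p under 0.05), so that all 10 splits call as many and the count says nothing (highest other 0). Between stages 1 of 10 did in the adult group (512, highest other 1) and 1 of 10 in the prepubertal group (563, highest other 2). Any other split there mixes the stages within a group, so the difference between them enters the spread and lowers the count. These counts therefore do not measure chance. For the difference of the donor effect between stages the real split also called 0 with limma (1307 at an unadjusted p under 0.05), so that 100 of 100 drawn splits call as many whatever they hold, and that count says nothing either (highest other 11). For the ribosomal list the real size was 1.44 at the 8-16-cell stage (highest other 1.36) and 0.59 in blastocysts (highest other 0.38).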

How the results depend on the processing

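The floor at the highest background, the other limits for counting probe sets above background, that count without each array, bounds without an array, and counts of calls without each array of the groups not compared were chosen after seeing the data; the rest, an estimated correlation among them, were planned. Signal over background limits what can be read: 6435, 3628, 6442 and 8329 probe sets on average were above it in adult and prepubertal 8-16-cell embryos and adult and prepubertal blastocysts, 569 were above it on all arrays, and a simulated change of 4 on the log2 scale was called in at most 18% of cases, all of them probe sets with a mean above the median. Where a call changed below, the cause was not tested.

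Of the named genes' results under the alternatives, 318 of 320 in the adult stage comparison and 318 of 320 in the prepubertal one kept their direction and side of the threshold, as did 294 of 350 between donor groups at the 8-16-cell stage (38 lost the call, 18 gained one), 301 of 302 in blastocysts and 103 of 104 for the difference between stages. At the 8-16-cell stage only 5 of the 23 results were calls, and all 38 losses were theirs. In blastocysts and for the difference between stages no result was a call, so those shares say only that values stayed short of the threshold. Of the lists' results, in the same order, 125 of 156, 111 of 117, 52 of 78, 10 of 13 and 58 of 76 kept their direction and side of the threshold, and the others did not pass. The 1 reversal was in probe sets above background: with a fixed signal of 2000 prepubertal minus adult was -425 at the 8-16-cell stage and -78.7 in blastocysts, while with the 95th percentile of the control probe sets both kept their direction. The difference of these between stages, 4694, was 347 with the fixed signal (exact permutation test, p = 0.315) and 3507 to 5546 leaving out an array, and the difference at the 8-16-cell stage was -3659 to -1620.

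Between donor groups at the 8-16-cell stage 5 probe sets were called: 8 after quantile normalization, 17 with each array centred on its median, 3 with an offset of 1, 3 with an offset of 64, 1 with the floor, 0 by limma without the 40% of probe sets of lowest mean, 0 with a variance prior without a trend (2166 at an unadjusted p under 0.05 in the main model), 3 with array weights, 2 with only the 2 groups compared, 2 with a replicate block, 2165 at an unadjusted p under 0.05 and 2-fold, 10 at an adjusted p under 0.1, 2 to 14 leaving out an array compared, and 2 to 5 leaving out another. In blastocysts 0 became 2 with only the 2 groups compared and 883 at an unadjusted p under 0.05 and 2-fold. For the difference between stages 0 became 1307 under that rule and 0 to 1 leaving out an array. In the adult stage comparison 512 became 889 with array weights, 2674 at an unadjusted p under 0.05 and 2-fold, 816 at an adjusted p under 0.1, 253 to 408 leaving out an array compared and 469 to 794 leaving out another, the highest without prepubertal 8-16-cell replicate 3. In the prepubertal one 563 became 3305, 902, 272 to 536 and, leaving out an array not compared, 517 to 611. A replicate block gave 533 and 582 there. No pairing by replicate number was seen, since deviations of the same number correlated within 0.05 of 0, as did those of other numbers. With 3 arrays per group this cannot exclude shared animals, a shared bull or a shared day of culture.

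Lists called between donor groups at the 8-16-cell stage numbered 6, but 0 with an estimated correlation, 0 by fry, 0 with the floor and 3 to 7 leaving out an array. In blastocysts 1 became 0, 0, 3 with the floor and 0 to 1. For the difference between stages 4 became 0, 0 and 2 to 5. In the adult stage comparison 12 became 3 with an estimated correlation and 5 with the floor, and in the prepubertal one 9 became 5 with the floor.

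An estimated correlation and fry leave a list's median as it is, and fry asks whether the list changed at all, not whether it differs from other genes, so its p is no test of the medians below. At the 8-16-cell stage an estimated correlation ended the calls between donor groups, and fry called no change, of heat shock (-1.07; fry adjusted p = 0.354), epigenetic regulators (-0.94; 0.29), ribosomal proteins (-1.44; 0.239), oxidative phosphorylation (-0.88; 0.428), proteasome (-1.64; 0.239) and spliceosome (-1.04; 0.29). The same held for ribosomal proteins in blastocysts (0.59; 0.675) and for the difference between stages of ribosomal proteins (1.81; 0.252), oxidative phosphorylation (1.48; 0.482), proteasome (1.76; 0.335) and spliceosome (0.81; 0.482). In the adult stage comparison an estimated correlation ended primitive endoderm (0.74), glycolysis (1.04), antioxidant (1.24), heat shock (1.31), cholesterol (0.79), cell cycle (-1.41), ribosomal proteins (1.61), proteasome (1.26) and spliceosome (-0.57; fry 0.334), and in the prepubertal one primitive endoderm (1.46).

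Quantile normalization ended heat shock (-0.60, adjusted p = 0.127) and epigenetic regulators (-0.66, 0.102) between donor groups at the 8-16-cell stage, and the adult spliceosome (-0.43, 0.0766). The floor at the highest background ended heat shock (-0.12, adjusted p = 0.963), epigenetic regulators (-0.23, 0.077), ribosomal proteins (-0.28, 0.077), oxidative phosphorylation (0, 0.753), proteasome (-0.21, 0.753) and spliceosome (-0.25, 0.753) at the 8-16-cell stage, and for the difference between stages proteasome (0.24, 0.38) and spliceosome (0.17, 0.686). It ended in the adult stage comparison maternal transcripts (-0.083, 0.142), primitive endoderm (0.69, 0.0538), glycolysis (0.25, 0.447), antioxidant (0.41, 0.286), cholesterol (0.36, 0.302), proteasome (0.33, 0.302) and spliceosome (-0.73, 0.0538), and in the prepubertal one primitive endoderm (1.11, 0.095), glycolysis (0.91, 0.0986), heat shock (0.77, 0.132), cholesterol (0.21, 0.439) and proteasome (0.66, 0.0664). Leaving out the 40% of probe sets of lowest mean ended epigenetic regulators at the 8-16-cell stage (-1.17, 0.0728), the spliceosome difference between stages (0.66, 0.13), and adult antioxidant (1.30, 0.111) and proteasome (1.01, 0.0967). The mean of all probe sets of a gene ended the spliceosome difference between stages (0.44, 0.0803) and the adult spliceosome (-0.49, 0.122).

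Leaving out each array in turn gave ranges, each with at least 1 array that ended the call, of -1.51 to -0.24 for heat shock, -1.12 to -0.37 for epigenetic regulators and -1.33 to -0.39 for the spliceosome between donor groups at the 8-16-cell stage, 0.43 to 0.78 for ribosomal proteins in blastocysts, and 1.32 to 2.02 for the proteasome and 0.29 to 1.11 for the spliceosome for the difference between stages. In the adult stage comparison they were 0.45 to 1.07 for primitive endoderm, 0.90 to 1.30 for antioxidant, 0.93 to 1.58 for proteasome and -0.88 to -0.36 for spliceosome.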

Other observations

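The genes of the first paragraphs were chosen after their values were seen; the test of the last paragraph was planned.

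The genes below were picked among those called in both donor groups, so that they changed in both by choice, and no group of genes was tested. ACTG1, a cytoplasmic actin, rose from the 8-16-cell stage to the blastocyst by 6.87 (SE 1.01, adjusted p = 5.26e-07) in the adult and by 5.83 (adjusted p = 2e-05) in the prepubertal group, the tropomyosin gene TPM1 by 7.31 (SE 1.44) and 6.77, the myosin light chain gene MYL6 by 5.12 (SE 1.21) and 4.46, and ACTB by 2.46 (SE 0.70) and 4.28. The basement membrane gene NID1 rose at least 54.0-fold and 3.13-fold, the membrane-binding genes ANXA2 at least 35.3-fold in the adult group and by 6.41 (SE 1.42) in the prepubertal, and ANXA1 at least 8.38-fold and 6.75-fold. The peptidase gene ENPEP rose at least 28.9-fold and 6.32-fold, and PRL, read as the prolactin gene, at least 21.3-fold and 9.74-fold, although of its 5 other probe sets 1 had the same direction in the adult and 3 in the prepubertal group. The iron store gene FTH1 rose by 4.05 (SE 0.82) and 6.96, and the mitochondrial carrier and channel genes SLC25A5 and VDAC2 by 5.18 (SE 1.20) and 3.77 (SE 0.97) in the adult group and by 7.34 and 5.56 in the prepubertal, where the other probe set of SLC25A5 went the other way. TPM1 in both donor groups, and ANXA2 and SLC25A5 in the prepubertal, were above background on 1 of 3 8-16-cell arrays, so these sizes rest in part on background.

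Picked in the same way among the genes that fell, NAMPT, of NAD synthesis, fell by 5.31 (SE 0.93, adjusted p = 4.33e-05) in the adult and 5.45 in the prepubertal group, while its other probe set went the other way in both without passing. Others that fell were the amino acid transporter gene SLC1A5 by 4.75 (SE 0.68) and 4.71, and SAT1, of polyamine breakdown, by 3.56 (SE 1.02) and 3.35. The elongation factor gene ELL2 fell by 5.01 (SE 0.89) and 4.86, TBPL1, related to the TATA-binding protein, by 5.81 (SE 1.03) and 6.08, and TOB1 and CNOT6, of mRNA deadenylation, by 5.36 (SE 1.44) and 5.59 (SE 1.41) in the adult and 5.62 and 5.92 in the prepubertal group, with CNOT6 above background on 1 of 3 adult blastocyst arrays. The spindle gene TACC3 fell by 3.06 (SE 0.81) and 4.55.

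One hypothesis was that prepubertal 8-16-cell embryos may be behind in development, which would leave genes that fall toward the blastocyst higher in them and genes that rise lower. Genes were picked with 1 adult array left out and read on that array and 1 prepubertal array, in 9 pairs, with 394 to 528 rising and 220 to 269 falling genes. The mean over pairs of the median difference was -0.024 for falling genes (-0.62 to 0.74, above 0 in 5 of 9) and -0.19 for rising genes (-0.54 to 0.26, below 0 in 7 of 9). The rule written beforehand counted a median of 0 or below for falling genes against the hypothesis, and the mean of -0.024 meets it. As run, the test also asked for a mean of 0 or below whichever adult array was left out, which did not hold. With pairs that share arrays and lie on both sides of 0, the hypothesis stays open.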
